A study of Homo sapiens with 7 samples.

How the data were processed

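The comparison uses 5 RNA-seq libraries of MDA-MB-231 cells, 2 of the group labelled KD and 3 of the group labelled parent. The series also holds 2 chromatin immunoprecipitation samples, an input and an APE1 sample with 1 library each, which were not analysed here. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They do not spell out the abbreviation KD either, and the treatment protocol describes APE1-knockout cells given APE1 back from a doxycycline-inducible vector. Per the labels' protocols, total RNA was extracted on silica columns, and libraries were made and sequenced at a core facility.

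The authors deposited a gene table and a transcript table of expected counts, in whole numbers. The submitters' processing notes name STAR, DESeq2 and the genome build hg19, without versions. The counting tool, the annotation and the use of strand are not given in the sources used here. The gene totals equalled the transcript totals in each library, so both tables divide the same reads. The third deposited table holds the authors' own comparison. Per the file headers, it gives a mean signal over normalised counts, a log2 fold change with its standard error, a test score (the Wald statistic), and a p-value with its adjusted form.

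Library totals were 14677006 and 15502425 counts in KD replicates 1 and 2, and 15890435, 14601078 and 18049386 counts in parent replicates 1, 2 and 3. Between 22725 and 23623 genes had at least 1 count in a library. The 10 most abundant genes took 3.82% to 4.14% of the counts. All 37 genes with a mitochondrial-genome symbol are listed at 0 in each library, so they give no measure of RNA quality here. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom over genes was at least 4.31 in the 4 pairs within a group. Over log2 CPM, r across genes was 0.981 to 0.983 within a group and 0.949 to 0.954 between groups. Genes are not independent replicates. The first principal component held 64.4% of the variance and separated KD from parent. The second held 13.9% and set KD replicate 1 (score 31.0) apart from KD replicate 2 (-30.6), with parent replicates 1, 2 and 3 at 12.5, 2.83 and -15.8.

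The gene table has 57773 rows, of which 28957 were at 0 in all 5 libraries. Gene names are those of the file, and 51996 of the identifiers matched the name table used here. Low counts were removed with filterByExpr at its default settings (minimum count 10, minimum total 15), which left 16198 genes. Counts were scaled with TMM factors, and KD was compared with parent by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term. This left 3 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the root of the F statistic. Levels are CPM on TMM-scaled libraries, as mean ± SD. For a gene at 0 in a whole group, the fold is a lower bound against 3 counts over that group, which is 0.0988 CPM in KD and 0.0623 CPM in parent. Such floors cover counting error only. Transcripts were tested in the same way, on 42700 of 196354 rows. No map from transcripts to genes was used, so no transcript is named.

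Before the data were examined, 34 gene lists with 1022 distinct symbols were written, and 33 had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Fry tests whether the genes of a list move, on balance, 1 way, and does not compare the list with other genes. Genes were named by a rule fixed at the same time. It takes APEX1. It takes the 10 highest and 10 lowest fold changes among called genes with a protein-coding type of symbol, at least 5 CPM in 1 group and no overlap between groups. It also takes the 5 most abundant called genes, and the members of each list with the smallest adjusted p, up to 4 in a list past the threshold and up to 2 in another. A gene outside the rule is marked where it appears.

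The code was tested on simulated counts for the KD against parent comparison, drawn from the real means and library totals. With 200 of 15895 genes changed, 68.7% of the 1.5-fold, 88.1% of the 2-fold and 92.4% of the 4-fold changes were recovered in the right direction. Of the calls, 14.4% were genes that had not been changed, more than the nominal 5%. The changed genes were a smaller share than the 21.5% called in the data, so this value need not hold for the real calls. With 200 of 38145 transcripts changed, 6% of the 2-fold, 26% of the 4-fold, 22% of the 16-fold and 50% of the 64-fold changes were recovered. Changes were placed only in genes and transcripts above a minimum mean count, so recovery at lower counts was not measured.

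Alternatives were the size factors of DESeq2 1.42.0 within edgeR, library totals alone, no filter, CPM above 1 in at least 2 libraries, the replicate number as a block, each replicate left out in turn, the DESeq2 Wald test and limma-voom. Fits without the genes at 0 in both KD libraries were added after the data had been seen. Bias by gene length or GC content was not examined, since no annotation of hg19 was used here. The order of neighbouring genes came from a RefSeq table on GRCh38, used for names and order only.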

Results

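The series concerns APE1 (apurinic/apyrimidinic endonuclease 1), the base excision repair enzyme that cuts DNA at sites that have lost a base and that also acts on the redox state of transcription factors. Its title asks how the binding of APE1 to G-quadruplexes, 4-stranded structures of guanine-rich DNA, bears on metastasis of triple-negative breast cancer. Gene expression was measured by RNA-seq in MDA-MB-231, an established triple-negative breast cancer line with mesenchymal features. The data comprise 2 libraries labelled KD, with 14677006 and 15502425 counts, and 3 libraries labelled parent, with 14601078 to 18049386 counts. The comparison of KD with parent asks which transcripts differ between cells with reduced APE1 and the line they are set against. Levels are given as CPM, mean ± SD, with n = 2 for KD and n = 3 for parent.

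APEX1, the gene for APE1 (ENSG00000100823), was lower in both KD libraries than in each parent library. It had 640 and 753 counts in KD replicates 1 and 2, against 1936, 1936 and 2413 counts in parent replicates 1, 2 and 3. The level was 45.8 ± 3.48 CPM in KD and 130.3 ± 5.84 CPM in parent, so that 0.352 of the parent level was measured in KD. The log2 fold change was -1.51 ± 0.0727 (SE, edgeR quasi-likelihood test, adjusted p = 5.9e-05). The counts follow the labels. They do not show how much APE1 protein was present, and APEX1 transcript was still detected in the KD libraries.

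**Figure D1:**
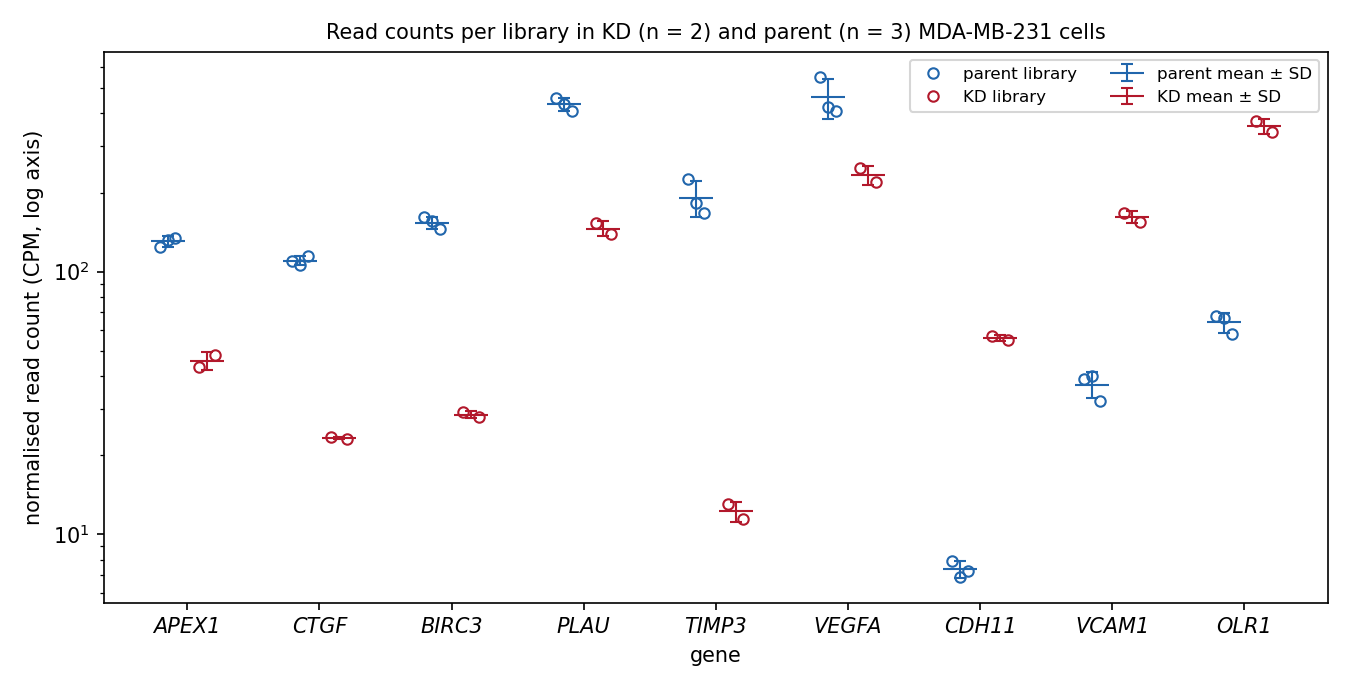
Normalised read count (CPM, log axis) of 9 genes in each library, with open circles for single libraries and a bar with whiskers for the mean ± SD of 3 parent (blue) and 2 KD (red) libraries. APEX1 fell from 130.3 to 45.8 CPM, CTGF, BIRC3, PLAU, TIMP3 and VEGFA were lower in both KD libraries than in any parent library, and CDH11, VCAM1 and OLR1 were higher in both.

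The named genes rose by up to 11.4-fold, and the 10 with the lowest fold changes were not detected in KD. The gene for the mesenchymal cadherin CDH11 was 7.60-fold higher in KD, at 55.9 ± 1.52 against 7.36 ± 0.518 CPM (edgeR adjusted p = 8.4e-06). VTN, the adhesive glycoprotein vitronectin, was 7.13-fold higher, at 306 ± 65.8 against 43.0 ± 9.69 CPM (edgeR adjusted p = 0.000205). The receptor for oxidised lipoprotein OLR1 was 5.57-fold higher and the cell adhesion molecule VCAM1 4.34-fold higher, reaching 358 ± 24.2 and 161 ± 8.64 CPM in KD. The cancer-testis antigen SSX1 had the highest rise of the named genes, 11.4-fold, but it belongs to a family of near-identical copies and its count is uncertain. ADAM12, TMEM52B, DIO2, RTN4RL1 and DUSP9 completed the 10 highest, at 5.16-fold to 6.23-fold. The 10 lowest genes were all at 0 counts in both KD libraries. LCP1, the actin-bundling protein L-plastin, had 131.8 ± 5.79 CPM in parent and was at least 1334-fold lower in KD. KYNU, the tryptophan-catabolic enzyme kynureninase, was at least 274-fold lower from 27.0 ± 2.42 CPM, and LYPD6B at least 259-fold lower from 25.6 ± 2.28 CPM. CES1, ARAP2, MBNL3, DSC2 (the desmosomal cadherin desmocollin 2), FRAS1, KCNS3 and PTN (the growth factor pleiotrophin) were at least 101-fold to 166-fold lower, from 9.98 to 16.4 CPM in parent. The edgeR adjusted p of these 10 genes was at most 0.00415. Their fold bounds cover counting error only, and would not hold where an estimate falls to 0 in single libraries. MBNL3 varied in the parent libraries (14.9 ± 7.54 CPM), and CES1 has a close pseudogene copy, which makes its count uncertain.

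Across all 16198 tested genes, 3485 (21.5%) passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 1482 higher and 2003 lower in KD. Of these, 899 differed at least 2-fold, 218 higher and 681 lower, and 167 of the lower ones were at 0 in both KD libraries. Among the 5 most abundant called genes, the ferritin heavy chain FTH1 was 1.71-fold higher (4192 ± 625 against 2446 ± 402 CPM) and the ferritin light chain FTL 1.21-fold higher. Cytoplasmic gamma-actin ACTG1 was 1.18-fold higher. The glycolytic enzyme PKM was 1.28-fold lower and the matrix protein thrombospondin 1, THBS1, 1.39-fold lower. FTH1 lost its call without KD replicate 1 (adjusted p = 0.0588, within a range of 0.00165 to 0.0588 over all alternatives). FTL lost it without KD replicate 1 (0.0989), parent replicate 2 (0.0839) or parent replicate 3 (0.0826), within 0.000435 to 0.0989. ACTG1 lost it without KD replicate 1 (0.0614) or parent replicate 1 (0.0531), 2 (0.0811) or 3 (0.0667), within 0.000344 to 0.0811. THBS1 lost it without KD replicate 1 (0.169), parent replicate 2 (0.0866) or parent replicate 3 (0.0827) and with no filter on low counts (0.0757), within 0.0226 to 0.169. The count of changed genes fell to 1823 without KD replicate 1, to 2076 without KD replicate 2 and to 2029 without parent replicate 2, with 553, 755 and 709 of them higher. Without KD replicate 1, 130 genes were at least 2-fold higher and 677 at least 2-fold lower.

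**Figure D2:**
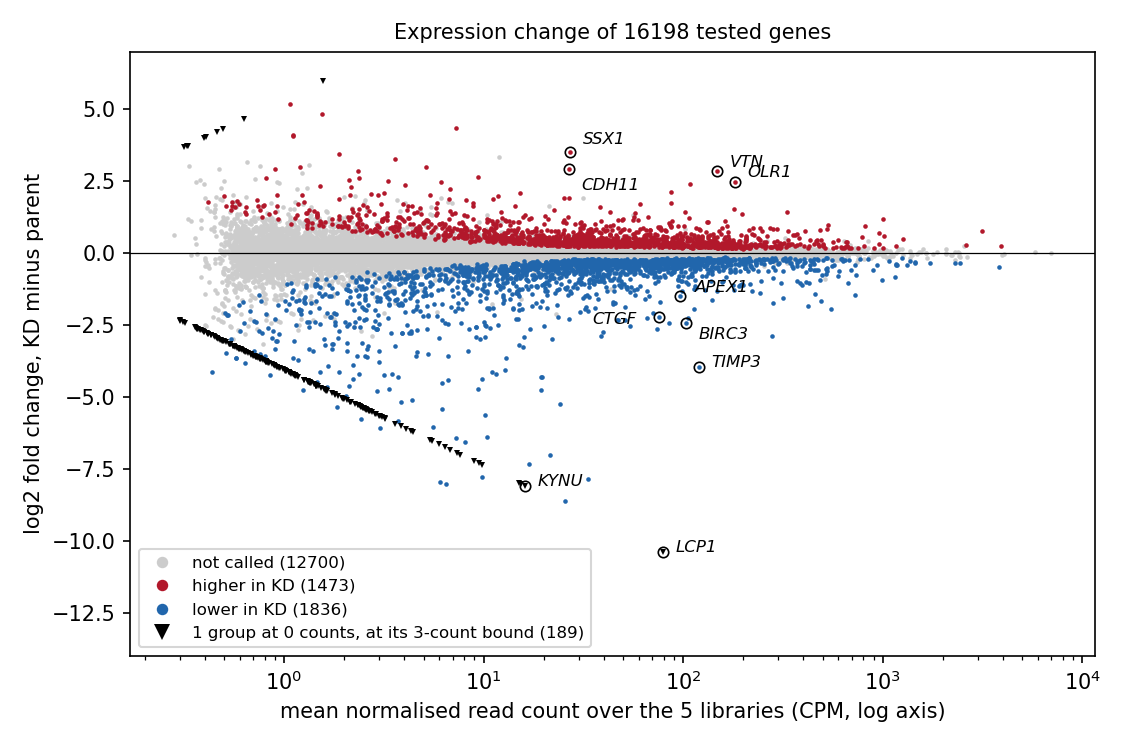
Log2 fold change (KD minus parent) of the 16198 tested genes against their mean normalised read count over the 5 libraries (CPM, log axis), with genes passing an adjusted p of 0.05 in red (higher in KD) and blue (lower), other genes in grey, and genes at 0 counts in 1 whole group as black triangles at their 3-count bound. The large differences lie mostly below 0, with 681 genes at least 2-fold lower and 218 at least 2-fold higher (677 and 130 without KD replicate 1).

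More members fell than rose in the lists of growth-factor-responsive, inflammatory and hypoxia genes. Of 30 tested AP-1 and immediate early genes, which respond within a short time to growth factors and stress, 19 fell and 1 rose (21 and 1 adjusted over the list alone), with a median log2 fold change of -0.60. DUSP5 and SPRY4, feedback inhibitors of ERK signalling, were 2.52-fold and 1.76-fold lower, the transcription factor MAFF was 2.16-fold lower, and PHLDA1 was 1.56-fold lower at 395 ± 19.4 against 618 ± 10.3 CPM. Of 30 NF-kB and inflammatory genes, 16 fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.32. Among them BIRC3, an inhibitor of cell death, was 5.38-fold lower, the chemokine CXCL1 4.10-fold lower, the cytokine IL1B 3.64-fold lower and G0S2 2.49-fold lower. Of 38 hypoxia genes, targets of the HIF transcription factors, 14 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -0.40. VEGFA, the angiogenic growth factor, was 1.97-fold lower at 234 ± 19.5 against 461 ± 80.0 CPM. The glycolytic enzyme ALDOC was 12.2-fold lower and ANKRD37 4.74-fold lower. The glucose transporter SLC2A1 fell from 532 ± 39.0 to 354 ± 16.4 CPM. Camera with a preset correlation gave adjusted p = 1.5e-05, 1.6e-05 and 0.000221 for these 3 lists, and adjusted p = 0.759, 0.766 and 0.998 with an estimated correlation. The estimated correlations were 0.026, 0.088 and 0.80, with unadjusted camera p = 0.0230, 0.0598 and 0.433. Fry gave the AP-1 and NF-kB lists adjusted p = 0.00243 and 0.00231, both lower. The hypoxia call was also lost without KD replicate 2 (adjusted p = 0.0620, within a range of 4.8e-09 to 0.998 over all alternatives), and fry gave that list adjusted p = 0.153. The hypoxia median was -0.66 without KD replicate 1, -0.27 without KD replicate 2 and -0.26 without parent replicate 1.

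More members fell than rose also in the lists of matrix proteases and their inhibitors, YAP targets and the migration machinery. Of 30 matrix proteases and inhibitors, 13 fell and 3 rose (13 and 4 adjusted over the list alone), with a median log2 fold change of -0.26. The protease inhibitor TIMP3 was 15.6-fold lower, at 12.2 ± 1.08 against 191 ± 29.9 CPM. The plasminogen activators PLAU and PLAT were 2.97-fold and 2.77-fold lower, whereas the metalloprotease ADAM12 was 5.61-fold higher. Of 28 YAP/TEAD targets, 14 fell and 5 rose (14 and 5 adjusted over the list alone), with a median of -0.30. The matricellular genes CTGF and CYR61 were 4.73-fold and 2.74-fold lower, the ecto-nucleotidase NT5E 3.34-fold lower, and the growth factor TGFB2 1.80-fold higher. Of 40 actin and migration genes, 13 fell and 3 rose (16 and 5 adjusted over the list alone), with a median of -0.12. WASF3, an activator of actin branching, was 2.71-fold lower and the focal adhesion protein PXN 1.48-fold lower, while the actin bundler FSCN1 was 1.77-fold higher and the myosin kinase MYLK 1.40-fold higher. Camera with a preset correlation gave adjusted p = 0.00417, 0.0342 and 0.0458 for these 3 lists, and adjusted p = 0.998, 0.904 and 0.766 with an estimated correlation. Without KD replicate 2 all 3 calls were lost (adjusted p = 0.0968, 0.0755 and 0.102), and the median of the matrix list was -0.09, against -0.55 without KD replicate 1. The actin call was also lost without KD replicate 1 (adjusted p = 0.0860), without parent replicate 3 (0.0757) and with library totals alone (0.0521), within a range of 0.00502 to 0.766.

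**Figure D3:**
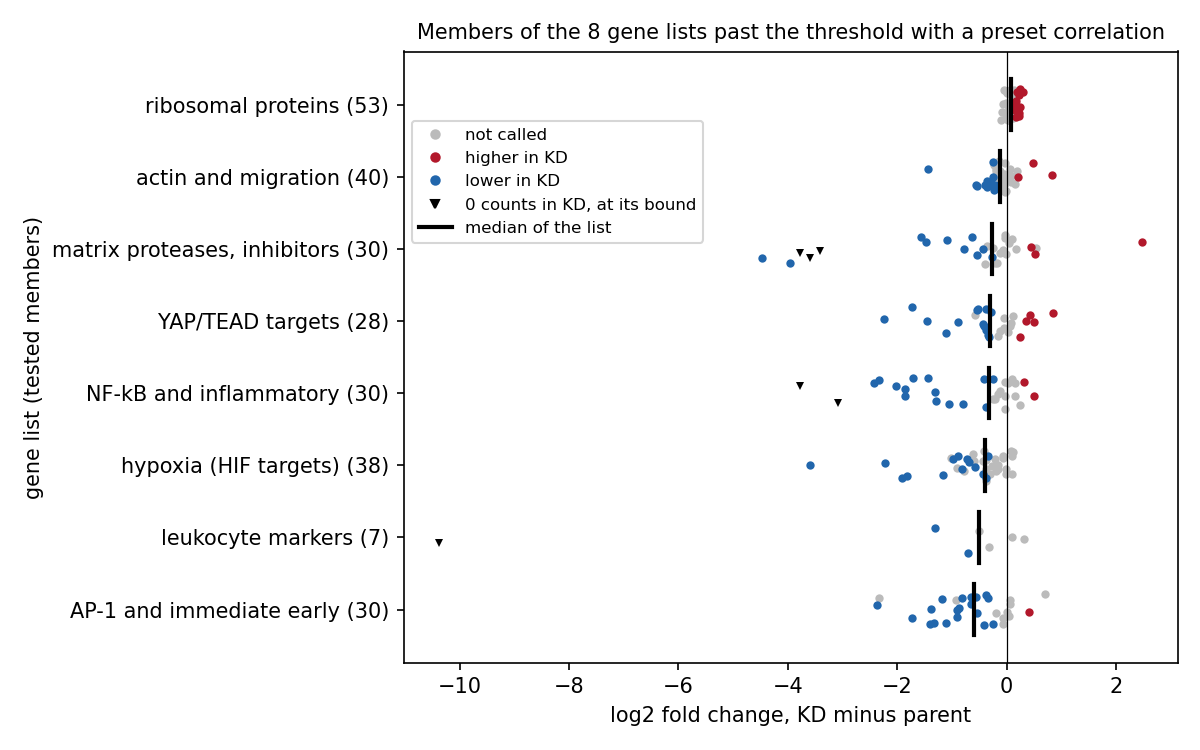
Log2 fold change (KD minus parent, horizontal axis) of every tested member of the 8 gene lists that passed with a preset correlation, 1 row per list with its number of tested members. Red and blue points passed an adjusted p of 0.05, grey points did not, triangles are genes at 0 counts in KD drawn at their bound, and the black bar is the list's median, from -0.60 for AP-1 and immediate early genes to 0.08 for ribosomal proteins.

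Genes tied to metastasis, adhesion and the mesenchymal state moved in both directions. Of 34 breast cancer metastasis genes, 9 rose and 15 fell (9 and 15 adjusted over the list alone, camera adjusted p = 0.0810). CDH11 was among those that rose and CTGF among those that fell, and 4 members, KYNU among them, were at 0 in KD. This list passed without KD replicate 1 (adjusted p = 0.0383) and with no filter on low counts (0.0198), within a range of 0.00231 to 0.909, the lower end from fry, which tests whether genes move on balance 1 way and does not compare them with other genes. Of 31 cell adhesion and integrin genes, 9 rose and 9 fell (11 and 10 adjusted over the list alone, camera adjusted p = 0.823). The collagen COL6A3 was 2.45-fold lower and the laminin receptor subunit ITGA6 1.49-fold lower. Of 29 mesenchymal genes, 8 rose and 7 fell (9 and 7 adjusted over the list alone, camera adjusted p = 0.340). S100A4, a calcium-binding protein of motile cells, was 3.13-fold lower at 61.2 ± 10.8 against 192 ± 16.4 CPM. Of 28 epithelial genes, 5 rose and 10 fell (7 and 10 adjusted over the list alone, camera adjusted p = 0.624). The epithelial transcription factor ELF3 was 3.13-fold higher and desmoplakin, DSP, 1.56-fold lower. Of 30 TGF-beta/SMAD targets, 9 rose and 10 fell (13 and 11 adjusted over the list alone, camera adjusted p = 0.823), with a median of 0.06 and a mean of -0.14. Of 21 WNT/beta-catenin targets, 5 rose and 9 fell (5 and 9 adjusted over the list alone, camera adjusted p = 0.340). Fry called this list lower (adjusted p = 0.00231), with a mean of -0.44 but a median of 0.02. The mean takes the 2 members at 0 in KD at their 3-count bound, with LEF1 at -6.50, and so depends on that floor. WNT7B was 8.06-fold lower, and the transcription factor LEF1 was at 0 in KD and at least 90.7-fold lower.

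Genes with G-quadruplex motifs described in their promoters, as the list was written from general knowledge, also moved both ways. Of 28 tested, 6 rose and 8 fell (7 and 10 adjusted over the list alone, camera adjusted p = 0.340). Fry called this list lower (adjusted p = 0.00243), with a median log2 fold change of -0.13. MYC was 1.60-fold lower, at 71.5 ± 4.39 against 115 ± 7.71 CPM (edgeR adjusted p = 0.00137). KDR, the VEGF receptor, was at 0 in KD and at least 42.9-fold lower from 4.24 ± 0.386 CPM. Of 25 G-quadruplex helicases and binding proteins, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.415), the transcription factor MAZ at 1.24-fold higher and the helicase BLM at 1.27-fold lower. Both calls were lost without KD replicate 1 (adjusted p = 0.0972 and 0.0931) and without KD replicate 2 (0.106 and 0.0850), and that of MAZ without parent replicate 2 (0.0680) and with no filter on low counts (0.0545), within ranges of 0.00175 to 0.106 and 0.0121 to 0.0931. Of the 28 other base excision repair genes, 1 passed the edgeR test (1 adjusted over the list alone, camera adjusted p = 0.823). It was the glycosylase MBD4, 1.40-fold higher at 36.6 ± 3.80 against 26.2 ± 0.358 CPM. PARP1 stood at 313 ± 24.5 in KD and 355 ± 17.6 CPM in parent (edgeR adjusted p = 0.105). Of 22 homologous recombination genes, 1 rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 0.157), and of 19 telomere genes 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.398).

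Few cell cycle genes passed the test. Of 46 G2/M and mitosis genes, 7 rose and 0 fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.0547), with the mitotic kinase AURKA 1.82-fold and the kinetochore protein NDC80 1.48-fold higher. The G2/M list passed without KD replicate 1 (adjusted p = 0.000388) and without parent replicate 3 (0.0323), within a range of 0.000388 to 0.998. Of 45 G1/S and replication genes, 2 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.990). The one that fell was cyclin D1, CCND1, 1.65-fold lower. Of 31 p53 targets, 2 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.989), with a median of 0.06 and a mean of -0.13. PMAIP1 (NOXA) was 3.83-fold and CDKN1A (p21) 1.60-fold lower. Of 53 cytosolic ribosomal protein genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone), by small amounts, with a median log2 fold change of 0.08. RPLP2 was 1.23-fold higher and RPL8 1.18-fold higher. Camera gave this list adjusted p = 0.00417 with a preset correlation and adjusted p = 0.998 with an estimated correlation, and fry gave adjusted p = 0.117. The call on RPL8 was lost without KD replicate 2 (adjusted p = 0.0568, within a range of 2.2e-06 to 0.0568), and many ribosomal protein genes have near-identical pseudogenes, so their counts are uncertain. Of 36 ribosome biogenesis genes, 1 rose and 5 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.0547). That list passed without KD replicate 2 (adjusted p = 0.00748), without parent replicate 1 (0.00456), with no filter on low counts (0.0198) and, in a fit added after the data had been seen, without genes at 0 in KD (0.0404), within a range of 0.00456 to 0.998.

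Of 38 NRF2 and oxidative stress genes, 9 rose and 10 fell (9 and 10 adjusted over the list alone, camera adjusted p = 0.842; median 0.01, mean -0.07), with the cystine transporter SLC7A11 4.97-fold and thioredoxin reductase TXNRD1 1.51-fold lower. Of 33 ATF4 and amino acid response genes, 5 rose and 5 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.989 in the higher direction, median -0.02, mean -0.03), with the transcription factor CEBPB 1.84-fold higher. Of 29 unfolded protein response genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.723). Of 35 cholesterol synthesis and uptake genes, 2 rose and 8 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.145, fry 0.00243 and lower). Of 41 nuclear genes of oxidative phosphorylation, 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.652). Of 38 interferon-stimulated genes, 6 rose and 6 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.767, fry 0.0339 and lower). IFI27 was 5.64-fold lower, and IFI44 was at 0 in KD and at least 54.3-fold lower. Of 23 antigen presentation genes, 6 fell and 0 rose (7 and 2 adjusted over the list alone, camera adjusted p = 0.0547). This list passed without KD replicate 1 (adjusted p = 0.0262), without parent replicate 3 (0.0370), with no filter on low counts (0.0224) and, in a fit added after the data had been seen, without genes at 0 in KD (0.0404), within a range of 0.0110 (fry, lower) to 0.909. The checkpoint ligand CD274 (PD-L1) was 3.77-fold lower at 7.81 ± 0.257 against 29.4 ± 0.780 CPM, and the class II invariant chain CD74 3.17-fold lower at 214 ± 22.1 against 677 ± 48.3 CPM.

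Of 22 leukocyte markers 7 could be tested, and 3 of them fell (4 adjusted over the list alone) and 0 rose (1 adjusted over the list alone). They were LCP1, the lysosomal membrane protein LAPTM5 (2.47-fold lower, 95.4 ± 14.1 against 235 ± 18.9 CPM) and CD14 (1.64-fold lower). Camera gave the list adjusted p = 0.0342 with a preset correlation and adjusted p = 0.766 with an estimated correlation. Its median log2 fold change was -0.51, and -0.33 without KD replicate 1. Its call was lost without KD replicate 2 (adjusted p = 0.0622), without parent replicate 1 (0.0585) and, in a fit added after the data had been seen, without genes at 0 in KD (0.208), within a range of 0.000142 to 0.766. The call on CD14 was lost with no filter on low counts (adjusted p = 0.0627), with limma-voom (0.0537), and without KD replicate 1 (adjusted p = 0.0831), KD replicate 2 (0.181), parent replicate 1 (0.0675) or parent replicate 2 (0.109), within a range of 0.0106 to 0.181. Of 6 fibroblast and endothelial markers 1 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.198, fry 0.00502 and lower). Of 6 kidney and neural markers 1 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.823, fry 0.0346 and lower), and of 12 luminal breast markers 3 rose and 4 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.842).

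At the level of single transcripts, few differences could be resolved. Of 42700 tested transcripts, 52 passed an adjusted p of 0.05 in edgeR, 10 higher and 42 lower in KD, and 4186 had an unadjusted p under 0.05. Transcript counts share reads between isoforms and are estimates. Their coefficient of biological variation was 0.833, against 0.0956 for genes. Leaving out any 1 library, whether KD replicate 1 or 2 or parent replicate 1, 2 or 3, left 0 transcripts past the threshold (3824 to 4787 with an unadjusted p under 0.05), whereas the DESeq2 Wald test called 2711. The 52 calls thus rest on all 5 libraries together and on the tool.

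The authors' deposited table holds 19816 genes with an adjusted p, of which 2693 were under 0.05, 976 higher and 1717 lower in KD. In the authors' deposited table APEX1 had a log2 fold change of -1.52 and an adjusted p of 3.8e-54. Of the calls in the authors' deposited table, 2558 were also called by edgeR here, all 2558 in the same direction. Another 135 were not called by edgeR, 63 of them because the filter on low counts had removed them, and 927 genes were called by edgeR alone. A DESeq2 run on the deposited counts gave 2693 calls, all shared with the authors' deposited table, with log2 fold changes that differed by at most 0.000119.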

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

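No called result reversed its direction under any alternative. Planned before the data were examined were all alternatives except the fits without genes at 0 in both KD libraries, which were chosen after the data had been seen. APEX1 kept its call in all 13 (log2 fold change -1.59 to -1.43 with 1 replicate left out). Of 94 other called genes named by the rule, 16 lost their call in at least 1 fit without a replicate and 5 in another fit, and 1 uncalled gene, CD8A, gained one. With 1 KD library left out, the lone KD library is assumed to vary like the parent libraries.

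Changed genes numbered 1823 to 3383 with 1 replicate left out, against 3485, and 2762 to 3940 in the other fits. At 2-fold or more they numbered 787 to 895 and 726 to 939, against 899. The low counts came without KD replicate 1 (1823), parent replicate 2 (2029) and KD replicate 2 (2076), and without parent replicate 1 the count was 3383. Fewer libraries leave fewer residual degrees of freedom, and why the libraries differ in this was not tested. The DESeq2 Wald test kept 2947 and limma-voom 3324 of the 3485 calls. Without the genes at 0 in both KD libraries, 3249 genes and 9 lists passed.

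Called gene lists numbered 4 to 10 with 1 replicate left out (4 without KD replicate 2), against 8. With an estimated correlation camera called 0 lists (1 at an unadjusted p under 0.05), and fry called 14, all lower. The estimated correlation was 0.80 for the hypoxia list but -0.09 for the leukocyte list, which is under the preset 0.01. The unadjusted camera p of the leukocyte list still rose, from 0.00725 with the preset to 0.0699. A higher correlation therefore does not account for that loss, and its cause was not tested. Fry's 14 included 6 of the 8, all but the hypoxia and ribosomal protein lists.

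Changed transcripts were 0 with each replicate left out, 0 with no filter (5659 at an unadjusted p under 0.05), 54 with DESeq2 size factors and 2711 with the DESeq2 Wald test. The cause was not tested. At a 4-fold change only 26% of simulated transcripts were recovered, which limits this result.

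The numbers 1 and 2 are shared by both groups, but the labels do not say that they mark a shared day or culture, and the deviations of same-numbered libraries had r = 0.039 across genes. With a replicate block, 3940 genes, 923 of them at least 2-fold, 7 lists and 0 transcripts (2615 at an unadjusted p under 0.05) passed, and APEX1 had a log2 fold change of -1.48. The number of parent replicate 3 occurs in no KD library, so the block fits that library exactly. The difference between groups then comes from replicates 1 and 2 alone. The block ended the calls on the actin list (adjusted p = 0.0746), the YAP/TEAD list (0.0564) and ACTG1 (0.0610), and the G2/M list passed (0.0256). The shared calls with the authors' deposited table numbered 2558 with edgeR and 2693 with DESeq2.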

Other observations

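The tests of leukocyte markers, of symbol stems and of estimates that fall to 0, and the camera tests of the ERK and class II genes, were chosen only after the results they bear on had been seen. The other tests were fixed before the values they measure were seen.

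Gene families sharing a symbol stem were searched for calls beyond those of all 12635 tested protein-coding genes (Fisher's exact test, 284 tests). None passed adjustment. The KLF transcription factors came closest, with 8 of 15 members lower where 2.24 would be expected (adjusted p = 0.157), together with the SLC transporters, with 39 of 224 higher where 23.6 would be expected (adjusted p = 0.157).

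HLA-DRA, a chain of the MHC class II antigen-presenting molecule, had 5 and 3 counts in the KD libraries and 514 to 615 in the parent libraries. CD74 was 3.17-fold lower, and CIITA, the master regulator of class II transcription, was 1.98-fold lower at 23.8 ± 4.56 against 47.1 ± 3.16 CPM. HLA-DRA and CIITA lie outside the rule for named genes and were picked after their values were seen. Of 11 other class II genes written down before their values were read, 7 could be tested. All 7 were lower in KD (edgeR), with a median log2 fold change of -3.30, a value set by HLA-DOA at its bound, and HLA-DPA1 was 9.60-fold lower. Camera gave unadjusted p = 5.0e-08 with a preset and 0.0601 with an estimated correlation. A lower output of the CIITA-driven class II genes is a candidate explanation as a hypothesis. CIITA itself fell 1.98-fold, against 135-fold for HLA-DRA. Reads shared between HLA-DRB1 and HLA-DRB5 make those counts uncertain. A change local to the class II gene cluster stays open and untested. CD74 lies on another chromosome, but it fell less (3.17-fold) than HLA-DRA and each of the 7 other tested class II genes, of which HLA-DMB fell least (3.61-fold).

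In 135 genes, the KD libraries had 0 counts while the parent libraries averaged 1 CPM or more, and the reverse held for 5 genes. Leukocytes in the parent cultures would bring their other abundant transcripts, but 15 of the 22 leukocyte markers stood below 1% of the LCP1 level, and PTPRC, CD53 and TYROBP were at 0 in all libraries. Loss of chromosome segments holding several genes would lower the neighbours too, yet the nearest tested genes had a median log2 fold change of -0.13 (95% bootstrap interval -0.18 to -0.09). Such loss stays open for part of the genes, since 26.3% of the 262 neighbours were called lower, against 13.1% of the genes placed in order, and 12 were at 0 in KD where random matched lists gave a median of 2. Estimates that fall to 0 in single libraries stay open too: 95 tested genes were at 0 in a parent library with 20 or more counts in another, 56 were split in this way between the KD libraries, and of 165 genes at 0 in both KD libraries with 20 or more counts in a parent library, 31 (18.8%, exact 95% interval 13.1% to 25.6%) were at 0 in another parent library. Of the 135 genes themselves, 5 (3.70%, exact 95% interval 1.21% to 8.43%) were at 0 in a parent library. The minimum on their parent mean selects against such zeros, so this lower share does not decide the question. Selection of a subpopulation of the parent line while the KD cells were made could give the same pattern as lower APE1. The design cannot separate them, because the labels mark no second KD line and no library with APE1 restored. Whether the KD libraries themselves carry restored APE1 is not stated in the labels.

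The AP-1, NF-kB and hypoxia lists passed as lower in camera with a preset correlation but not with an estimated one (adjusted p = 0.759, 0.766 and 0.998). The estimates were 0.026, 0.088 and 0.80, so the preset 0.01 was furthest off for the hypoxia list. The lists were set against the scaling of the libraries and against a lower output of the ERK pathway. The lists stayed lower under the scalings tried: under DESeq2 size factors and library totals, the highest of the 3 medians was -0.30. These scalings differed little, with TMM factors of 0.987 to 1.01. The median over all tested genes was -0.0041 with DESeq2 size factors and 0.0196 with library totals. They could hardly have moved the list medians, so an error of scaling common to them stays open. Of 17 other ERK target genes, in none of the fixed lists, 16 were tested, 8 fell and 2 rose, with a median log2 fold change of -0.33. None of 10000 random lists matched on expression had a median as low, a comparison that takes genes as independent, and camera gave unadjusted p = 0.00651 with a preset and 0.0616 with an estimated correlation. Lower ERK output stays a candidate explanation as a hypothesis. The ERK target genes do not measure NF-kB or HIF activity, so a part of ERK in the NF-kB and hypoxia lists was not tested. Neither an effect of culture density or medium on the same genes nor an action of APE1 on the redox state of transcription factors was tested.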
